A study of Homo sapiens with 9 samples.

How the data were processed

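RNA was measured by stranded total RNA sequencing, after removal of ribosomal RNA and with paired reads of 75 bases per the labels' protocols, in 9 cultures of MCF10A, an immortalised line of human breast epithelial cells. Per the labels, all cultures carried ectopic MYC and a mutant form of PI3K, and each held a hairpin construct that was induced with 2 µg/mL doxycycline for 72 hours. The groups were taken from the sample titles: a scrambled control hairpin (shSCR) and 2 hairpins against EHMT2, the gene of the histone methyltransferase G9a (shG9a_1 and shG9a_4), with 3 replicates each. The series' design text calls the replicates biological.

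The authors deposited, per library, whole-number counts of reads per gene, per the file headers, in the layout that the aligner STAR writes, with unstranded, sense-strand and reverse-strand columns. The submitters' processing notes name STAR 2.5.2a, edgeR 3.14.0, R 3.3.1, DESeq, GRCh37 and hg19, without a role or an order. The annotation release, any trimming and the alignment settings are not given in the sources used here. That layout assigns a read only where it maps to a single place, so genes with near-identical copies are uncertain. Among the genes named in the report these are PRDX3, RHEB, PIK3CA, NPM1, PCNA, KRT14, SAA1, SPRR2A, PCDHA12, MT-ND1, H1-1 and H2BC14. Counts of MYC and PIK3CA cannot separate the endogenous gene from the ectopic construct. The authors also deposited a table for each hairpin against shSCR with, per the file headers, posterior probabilities of equal and of different expression (PPEE and PPDE, scores from 0 to 1) and a smoothed and an unsmoothed linear fold (PostFC and RealFC, ratios). Their columns add no replicate values, and the tool that made them is not given in the sources used here.

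The reverse-strand counts were used, since 94.7 to 95.1% of the reads on the stranded columns lay there. Reads in genes came to 64478683, 76698004 and 53065611 in the shSCR libraries, to 62486212, 67353542 and 54477100 in shG9a_1, and to 76958831, 63501259 and 53583483 in shG9a_4. The 4 summary classes that name no gene were kept out of library sizes and tests. They held 12.2 to 15.4% of read pairs (no feature), 2.49 to 2.68% (ambiguous), 4.58 to 5.49% (multimapped) and 2.75 to 4.34% (unmapped). Of 60308 gene IDs, 40308 were named from a table of gene names and 498 from GENCODE release 29, and 97.5% of the reads lay on IDs with a symbol. That release is on another genome build than the files, so no coordinates are given, and it served only for symbols, biotypes and 3' UTR sequences. No pair of replicates was a duplicate: over genes with at least 20 reads, the chi-square per degree of freedom between libraries of a group was 25.2 to 78.9.

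Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test with TMM scaling and the filterByExpr filter, which left 18435 genes. A single fit held all 9 libraries with a mean per group, so that the groups shared an estimate of the spread with 6 residual degrees of freedom. Each hairpin was compared with shSCR and shG9a_4 with shG9a_1, two-sided, and p-values were adjusted by Benjamini and Hochberg at a threshold of 0.05. Every adjusted p of a gene is from edgeR unless another tool is named. Levels are given in CPM (read counts scaled by library size), and the SE of a log2 fold change comes from the fit, with a median of 0.154 for each hairpin against shSCR. Shares of reads were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3.

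The replicate numbers of the labels pair the libraries, as the data show. The deviations of libraries from their group means correlated at 0.178 to 0.461 in all 9 pairs of the same number, with a mean of 0.304, against a mean of −0.152 in the 18 other pairs. Since deviations cancel out within a group, the negative mean largely follows from the positive one and is no separate evidence. All 9 libraries correlated best with their own number. The numbers were not tied to a day or batch by any label. The fit without the number stayed the main one, as the design had fixed it, and the fit with the number as a block, which leaves 4 residual degrees of freedom, is given where it changed a result.

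The design, the 30 gene lists, the rule for naming genes and most alternatives were set before the data were examined. The lists were written from general knowledge: H3K9 methylation machinery other than EHMT2, genes reported as MYC-repressed, genes reported as MYC-activated, ribosome biogenesis, interferon-stimulated genes, inflammatory and NF-kB targets, cholesterol biosynthesis, fatty acid synthesis, serine and one-carbon synthesis, ATF4 and amino acid response, unfolded protein response, p53 targets, DNA replication and G1/S genes, G2/M and mitosis genes, replication-dependent histone genes, hypoxia and glycolysis genes, mesenchymal and extracellular matrix genes, epithelial junction and luminal genes, basal and myoepithelial genes, epidermal differentiation genes, germline and cancer-testis genes, clustered protocadherins, imprinted genes, autophagy and lysosome genes, mitochondrially encoded genes, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, fibroblast markers, immune cell markers and endothelial markers. Lists with at least 5 measured genes, 28 of the 30, were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. The same test with an estimated correlation is given beside it.

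Genes were named by this rule: EHMT2, EHMT1, WIZ, ZNF644, MYC and PIK3CA always; the 10 largest rises and 10 largest falls past the threshold in both hairpins; the 6 largest of each past the threshold in a comparison whose groups do not overlap; up to 4 members of each list with the smallest p; and any count of 5 or fewer in full. Ranked genes had at least 1 CPM in the highest group, a symbol that is not a clone name, and a protein-coding biotype where one was known. The rule was applied to the fit with and without the block, and not all of the genes that it named are reported here.

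The alternatives were RLE and upper-quartile scaling, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the likelihood ratio test of edgeR, unstranded counts, only the groups compared, the replicate block, each library left out in turn, and, for lists, fry and an estimated correlation. A newer deviance in edgeR and further settings within the blocked fit were added after seeing the data. The gene test was tested on simulated counts with 200 changed genes. It recovered 34.7% of genes changed by a log2 fold of 0.5, 65.7% at 1 and 86.2% at 2 for shG9a_1 against shSCR (18145 genes). For shG9a_4 against shSCR it recovered 19.0, 72.2 and 90.5% (18131 genes), and between the hairpins 29.9, 63.6 and 80.6% (18107 genes). No call had the wrong sign. Unchanged genes were 7 of 127, 10 of 135 and 4 of 120 calls, and 8 of 121, 13 of 133 and 8 of 121 with the block. The simulated counts left out the pairing by replicate number. With 200 changed genes planted, more passed than the 7, 5 and 0 of the real data, where the same adjusted threshold asks for smaller p-values. The recovered shares are therefore not those to be had in the real data. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

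For the closing observations, 3' UTRs of at least 30 bases were searched for words of 7 bases carried by at least 100 genes. Log2 of CPM plus 0.5, for genes of at least 1 CPM, was compared between hairpin and shSCR libraries in a regression on each word with terms for 3' UTR length, GC content and mean level, and residuals were limited at 1. A word planted with an effect of 0.1 log2 ranked 1 in a simulated scan of 11394 genes.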

Results

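Gene expression was measured in 9 cultures of MCF10A breast epithelial cells with ectopic MYC and mutant PI3K. Each held a scrambled hairpin (shSCR) or 1 of 2 against EHMT2, the gene of the histone H3 lysine 9 methyltransferase G9a, with 3 cultures per hairpin. The series title names MYC, G9a and transcriptional repression, so the comparisons ask which genes differed after knockdown of EHMT2, and whether genes reported as MYC-repressed were among them. Reads in genes numbered 53065611 to 76958831 per library, with 26759 to 28346 genes detected. At this depth the median SE of a log2 fold change was 0.154.

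EHMT2 (ENSG00000204371.11), the target of both hairpins, was lower in all 6 knockdown libraries than in all 3 shSCR libraries. Its level was 51.1, 45.2 and 45.4 CPM in shSCR, 17.6, 22.6 and 21.03 CPM in shG9a_1, and 32.1, 27.2 and 33.5 CPM in shG9a_4. The means were 47.3 ± 3.35, 20.4 ± 2.59 and 30.9 ± 3.32 CPM (SD, n = 3 each). EHMT2 fell in shG9a_1, with a log2 fold change of −1.21 (SE 0.11, adjusted p = 0.00766 in edgeR). In shG9a_4 the log2 fold change was −0.61 (SE 0.11) and missed the threshold in edgeR over all genes, with an adjusted p of 0.259. It passed with DESeq2 (0.000701), the likelihood ratio test (0.00298) and no filter (2.24e-05), in a range over all settings of 2.24e-05 to 1. The call in shG9a_1 was lost without shSCR replicate 1 (adjusted p = 0.0611), shG9a_1 replicate 2 (0.0513) or shG9a_1 replicate 3 (0.0622), in a range over settings of 8.52e-25 to 0.0622. Its log2 fold change stayed at −1.29 to −1.11 in shG9a_1 and at −0.66 to −0.53 in shG9a_4.

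EHMT1, which encodes the partner of G9a in its complex, was at 45.3 ± 1.53, 44.6 ± 2.31 and 43.8 ± 5.87 CPM in shSCR, shG9a_1 and shG9a_4 (SD, n = 3 each). Its log2 fold changes were −0.020 and −0.047. WIZ and ZNF644, zinc finger proteins of the same complex, had log2 fold changes of 0.13 and −0.066 in shG9a_1 and of −0.031 and −0.26 in shG9a_4. MYC (ENSG00000136997.15), counted with its ectopic copy, was at 186 ± 17.8, 182 ± 14.4 and 183 ± 37.1 CPM, with log2 fold changes of −0.032 (SE 0.13) and −0.026. PIK3CA, which encodes a catalytic subunit of PI3K and was counted with any ectopic copy of it, was at 145 ± 20.2, 201 ± 17.1 and 200 ± 27.8 CPM. The log2 fold changes of PIK3CA were 0.47 (SE 0.12, adjusted p = 0.461 in edgeR) and 0.46 (1.00), and passed the threshold with the replicate block (0.00769 and 0.00974, in ranges over settings of 4.30e-05 to 1 and 0.000256 to 1). None of EHMT1, WIZ, ZNF644 and MYC passed it in either hairpin under any setting tried.

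Hairpin shG9a_1 was compared with shSCR to find what differed after the larger loss of EHMT2 mRNA. Beside EHMT2, 6 genes rose, among them 5 that also rose in shG9a_4. PRDX3, a mitochondrial peroxidase, went from 208 ± 18.3 to 344 ± 12.5 CPM (SD, n = 3 each), a log2 fold change of 0.72 (SE 0.09, adjusted p = 0.0301 in edgeR). RAB21, a small GTPase of early endosomes, went from 79.5 ± 5.20 to 130.6 ± 7.53 CPM, a log2 fold change of 0.72 (SE 0.09, adjusted p = 0.0273). TRIM37, a ubiquitin ligase, had a log2 fold change of 0.65 (SE 0.07, adjusted p = 0.0228), and ANO6, a calcium-activated phospholipid scramblase, one of 0.52 (SE 0.07, adjusted p = 0.0301). CCDC25, a membrane protein that binds extracellular DNA, had one of 0.51 (SE 0.07, adjusted p = 0.0301).

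**Figure D1:**
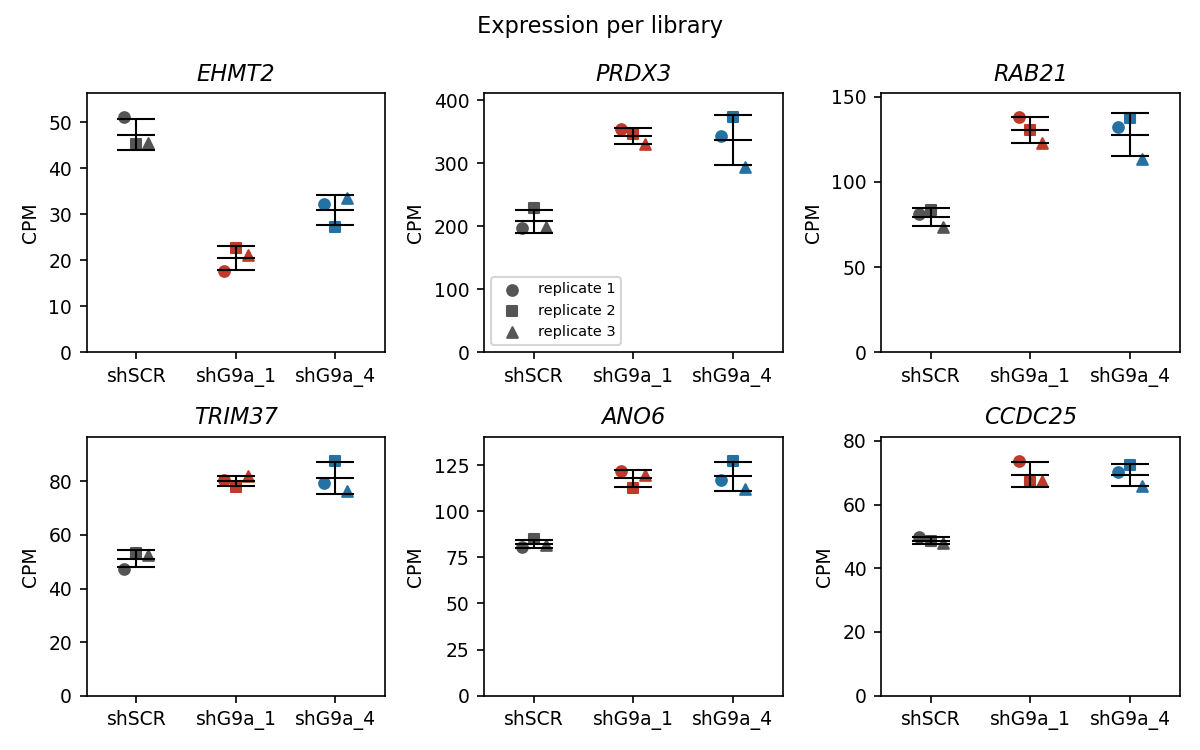
Level in CPM (read counts scaled by library size) of EHMT2, PRDX3, RAB21, TRIM37, ANO6 and CCDC25 in each of the 9 libraries by hairpin, with a symbol per replicate number and bars at the mean ± SD of 3 libraries. EHMT2 lay between 17.6 and 33.5 CPM in the knockdown libraries and at 45.2 CPM or more in shSCR, and the other genes lay higher in all 6 knockdown libraries than in all 3 shSCR libraries.

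In all, 7 of 18435 genes passed the threshold in shG9a_1 (6 higher, EHMT2 lower), and 1382 had an unadjusted p under 0.05 (2444 with the replicate block), where chance gives 922. The groups did not overlap for 2709 genes (14.7%, where chance gives 10%). The count came to 0 without shSCR replicate 1, shG9a_1 replicate 2 or shG9a_1 replicate 3, and to 1 without shSCR replicate 2 or 3, shG9a_1 replicate 1 or shG9a_4 replicate 1. Without each of these 7 libraries the calls of PRDX3, RAB21, TRIM37, ANO6 and CCDC25 were lost, at adjusted p-values of 0.0753 to 0.285 in edgeR. Over settings their log2 fold changes stayed at 0.69 to 0.80, 0.66 to 0.76, 0.60 to 0.68, 0.50 to 0.55 and 0.47 to 0.54. DESeq2 called 79 genes, the likelihood ratio test 42, no filter 288 and voom 7.

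With the replicate number as a block, 143 genes passed in shG9a_1 (119 higher, 24 lower), the 7 above among them. The largest rises were of SEZ6L2 (log2 fold change 1.57 without and 1.56 with the block), AZGP1, a secreted glycoprotein (1.41 and 1.44), KRT34, a hair keratin (1.33 and 1.32), RIMS2, a presynaptic scaffold protein (1.19 and 1.21), CDH16, a kidney cadherin (1.16 and 1.16), and PTHLH, which encodes parathyroid hormone-related protein (1.21 and 1.14). Their blocked adjusted p-values in edgeR were 0.0206, 0.0166, 0.0416, 0.0297, 0.0409 and 0.0466. The largest falls beside EHMT2 were of B4GALNT3, a glycosyltransferase (−0.98 and −0.97), COCH, an extracellular protein (−0.83 and −0.84), ZNF594 (−0.75 and −0.76), CLCN2, a chloride channel (−0.72 and −0.73), and MYB, a transcription factor (−0.63 and −0.63). Their blocked values were 0.0466, 0.0454, 0.0419, 0.0435 and 0.0454. Over all settings the adjusted p reached 0.618 for SEZ6L2, 0.906 for KRT34 and 1 for the other genes of both sets. Levels were low, under 1 CPM in a group, for SEZ6L2 (0.566 CPM in shSCR and 1.69 CPM in shG9a_1), AZGP1 (0.502 and 1.34), CDH16 (0.651 and 1.45), PTHLH (0.693 and 1.61) and B4GALNT3 (1.17 and 0.589). The blocked count was 4 without shSCR replicate 1, 43 without shSCR replicate 2, 7 without shSCR replicate 3, and 26, 238 and 4 without shG9a_1 replicates 1, 2 and 3. Without shG9a_4 replicates 1, 2 and 3 it was 40, 549 and 20.

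Genes reported as MYC-repressed were higher as a set in shG9a_1 than in shSCR, with 35 of 44 measured members higher and 9 lower and a median log2 fold change of 0.13. Among them were CDKN1A, which encodes the cell cycle inhibitor p21 (0.41, SE 0.13), and DUSP1, a phosphatase of MAP kinases (0.28, SE 0.09), neither past the threshold (adjusted p = 0.592 each in edgeR). The set rose in the camera test (adjusted p = 3.54e-05), at adjusted p = 0.219 with an estimated correlation. Genes reported as MYC-activated fell as a set, with 7 members higher and 49 lower, a median of −0.11 and an adjusted p of 3.03e-08. Their value was adjusted p = 0.324 with an estimated correlation. RCC1, a nuclear exchange factor of this list, had a log2 fold change of −0.19 (SE 0.06). Ribosome biogenesis genes fell as a set (6 higher, 35 lower, median −0.082, adjusted p = 2.22e-05), at adjusted p = 0.411 with an estimated correlation. The nucleolar proteins NOP56, NCL and NPM1 were at −0.18, −0.16 and −0.20. Cytosolic ribosomal proteins fell as a set by a median of −0.035 (11 higher, 36 lower, adjusted p = 0.0346), at adjusted p = 0.720 with an estimated correlation. That call was lost without shSCR replicate 1 (0.137), shSCR replicate 2 (0.416), shG9a_1 replicate 2 (0.0572), shG9a_1 replicate 3 (0.160) or shG9a_4 replicate 3 (0.0501), and with unstranded counts (0.0614). Over the settings that keep the preset correlation, the adjusted p ranged from 5.25e-06 to 0.00168 for MYC-repressed genes, 3.83e-09 to 0.000556 for MYC-activated genes and 0.000759 to 0.416 for ribosomal proteins.

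Cell cycle genes were lower in shG9a_1. DNA replication and G1/S genes fell as a set (3 higher, 43 lower, median −0.12, adjusted p = 3.03e-08 in camera), at adjusted p = 0.324 with an estimated correlation. GINS2 and MCM3, parts of the replicative helicase, were at −0.22 (SE 0.08) and −0.19. Replication-dependent histone genes fell as a set (1 higher, 27 lower, median −0.17, adjusted p = 9.34e-09), at adjusted p = 0.350 with an estimated correlation. H1-1 and H2BC14 were at −0.40 (SE 0.11) and −0.41 (SE 0.12), and H1-1 passed over all genes with the block (0.0337, in a range over settings of 0.00337 to 0.906). G2/M and mitosis genes fell as a set (11 higher, 37 lower, median −0.060, adjusted p = 0.00328), at adjusted p = 0.648 with an estimated correlation. Their call was lost without shG9a_1 replicate 1 (0.0938) or replicate 2 (0.304), in a range over settings of 2.96e-07 to 0.304. The p53 targets rose as a set (27 higher, 3 lower, median 0.14, adjusted p = 1.25e-05), at adjusted p = 0.330 with an estimated correlation. TP53I3, an oxidoreductase induced by p53, was at 60.1 CPM in shSCR and 88.4 CPM in shG9a_1. Its log2 fold change of 0.56 (SE 0.11) passed the threshold in edgeR when adjusted over the list alone (0.0158) and not over all genes (0.313, or 0.0301 with the block, in a range over settings of 2.57e-06 to 0.889).

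Amino acid synthesis genes were lower as well. Serine and one-carbon synthesis genes fell as a set in shG9a_1 (2 higher, 12 lower, median −0.14, adjusted p = 0.000120 in camera), at adjusted p = 0.324 with an estimated correlation. MTHFD1L, a mitochondrial folate enzyme, was at −0.24 (SE 0.07), and the serine synthesis enzymes PHGDH and PSAT1 were at −0.37 and −0.26. ATF4 and amino acid response genes fell as a set (2 higher, 26 lower, median −0.089, adjusted p = 0.00124), at adjusted p = 0.350 with an estimated correlation. This call was lost without shSCR replicate 1 (0.174, in a range over settings of 0.000135 to 0.174), and its members ASNS, asparagine synthetase, and ATF4 were at −0.32 (SE 0.09) and −0.28. The H3K9 methylation machinery other than EHMT2 fell as a set (4 higher, 18 lower, median −0.064, adjusted p = 0.0346), at adjusted p = 0.324 with an estimated correlation. Its call was lost without shSCR replicate 1 (0.236), shG9a_1 replicate 1 (0.0938) or shG9a_1 replicate 2 (0.0825), and with unstranded counts (0.0529), in a range of 0.0140 to 0.236. Autophagy and lysosome genes rose as a set (30 higher, 5 lower, median 0.074, adjusted p = 0.00154), at adjusted p = 0.219 with an estimated correlation. CTSB and SQSTM1, a protease of lysosomes and an autophagy receptor, were at 0.28 and 0.29. Autophagy and lysosome genes were the single list past the threshold with fry, which asks whether a set moves at all (0.0202).

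Immune and matrix genes were higher in shG9a_1. Interferon-stimulated genes rose as a set (40 higher, 10 lower, median 0.19, adjusted p = 1.41e-08 in camera), at adjusted p = 0.219 with an estimated correlation. PSMB8, a subunit of the immunoproteasome, was at 44.2 CPM in shSCR and 54.0 CPM in shG9a_1 (log2 fold change 0.29, SE 0.07, adjusted p = 0.380 in edgeR), the peptide transporter TAP1 was at 0.25 and IFI27 at 1.01 (SE 0.28). Inflammatory and NF-kB targets rose as a set (31 higher, 3 lower, median 0.31, adjusted p = 1.90e-05), at adjusted p = 0.497 with an estimated correlation. That call was lost without shG9a_1 replicate 2, where the median was 0.10 (0.0604, in a range over settings at the preset correlation of 7.97e-14 to 0.0604). The NF-kB subunits NFKB2 and RELB were at 0.21 and 0.32, the apoptosis inhibitor BIRC3 at 0.46 (SE 0.21) and SAA1, an acute-phase protein, at 0.42 (adjusted p = 0.669, or 0.0400 with the block, in a range over settings of 0.000427 to 1). PTGS2, the inducible cyclooxygenase, went against its list at −0.68 (0.828, or 0.0421 with the block, in a range of 1.57e-06 to 1). Mesenchymal and extracellular matrix genes rose as a set (32 higher, 4 lower, median 0.24, adjusted p = 7.59e-06), at adjusted p = 0.324 with an estimated correlation, and fibroblast markers, of another cell type, were higher beside them (7 of 7, median 0.39). MMP14, a membrane-bound metalloproteinase, was at 0.32 (SE 0.08), SPARC at 0.28, the integrin chain ITGA3 at 0.26, the collagen COL8A1 at 0.65 (SE 0.21) and TNC, a matrix glycoprotein, at 0.57 (SE 0.22). COL8A1 and TNC passed over all genes with the block (0.0427 and 0.0434, in ranges over settings of 9.56e-08 to 1 and 0.000329 to 1).

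Basal and myoepithelial genes rose as a set in shG9a_1 (20 higher, 5 lower, median 0.26, adjusted p = 2.22e-05 in camera), at adjusted p = 0.330 with an estimated correlation. KRT14, a keratin of basal cells, was at 33.4 ± 14.1 CPM in shSCR and 60.2 ± 23.1 CPM in shG9a_1 (SD, n = 3 each). Its log2 fold change was 0.85 (SE 0.34, adjusted p = 0.633 in edgeR, or 0.00576 with the block, in a range over settings of 4.10e-14 to 1). COL17A1, a collagen of hemidesmosomes, was at 0.30. Epidermal differentiation genes rose as a set (14 higher, 3 lower, median 0.27, adjusted p = 0.00249), at adjusted p = 0.324 with an estimated correlation, and the call was lost without shG9a_1 replicate 2 (0.0572, in a range of 5.43e-05 to 0.0572). The cornified envelope genes SPRR2A and SPRR1B went apart, at 1.23 (SE 0.50) and −1.03 (SE 0.36). Fibroblast markers, a cell type other than the line's own, rose as a set (7 higher, 0 lower, median 0.39, adjusted p = 0.0234), at adjusted p = 0.324 with an estimated correlation. PDPN, a membrane glycoprotein of that list, was at 0.39 (SE 0.14). The fibroblast call was lost without shSCR replicate 1 (0.0999), shSCR replicate 3 (0.0925) or shG9a_1 replicate 2 (0.165), in a range of 9.24e-05 to 0.165.

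In all, camera called 18 of the 28 tested lists in shG9a_1, 9 higher and 9 lower, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Of 818 measured members of the 30 lists, 0 passed the threshold over all genes in edgeR, and 96 had an unadjusted p under 0.05. DESeq2 called 4 of them (PSMB8, TP53I3, PCDHA12 and, lower, MEST), the likelihood ratio test 2 (TP53I3 and MEST) and voom 0. Adjusted over the list alone, edgeR called TP53I3, the protocadherin PCDHA12 (log2 fold change 0.68, SE 0.15, 0.0219), the endothelial receptors KDR (0.72, SE 0.25, 0.0484) and TEK (0.58, SE 0.24, 0.0496) and, lower, the imprinted gene MEST (−0.48, SE 0.09, 0.00452), and 0 members of the other lists. With the block, 11 members passed over all genes (7 higher, 4 lower), among them 3 mesenchymal and 2 histone genes and 1 epidermal gene, and 96 when adjusted over the list alone (78 higher, 18 lower). Of these, 19 NF-kB targets, 16 mesenchymal, 14 interferon-stimulated, 11 basal, 4 epidermal and 4 fibroblast genes were higher, and 5 histone and 4 serine synthesis genes lower. MEST, an imprinted hydrolase, was at 97.0 CPM in shSCR and 69.5 CPM in shG9a_1 and passed over all genes with the block (0.0108, or 0.223 without, in a range over settings of 5.81e-05 to 1).

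The other lists did not pass in shG9a_1. Cholesterol biosynthesis genes had 7 members higher and 17 lower (median −0.061, adjusted p = 0.279 in camera) and were called with the block (0.0272, or adjusted p = 0.631 with the block and an estimated correlation) and without shSCR replicate 2 (0.00911) or shG9a_1 replicate 3 (2.31e-06). Fatty acid synthesis genes (median −0.12, 0.369) were called without the same libraries (0.0102 and 0.00337). Hypoxia and glycolysis genes (median −0.032, 0.291) were called lower without shSCR replicate 3 (0.000403) or shG9a_1 replicate 2 (0.0132), and epithelial junction and luminal genes (0.043, 0.335) higher without shSCR replicate 3 (0.000363) or shG9a_1 replicate 1 (0.0159). The unfolded protein response (median 0.029, adjusted p = 0.252), mitochondrially encoded genes (−0.047, 0.777) and nuclear genes of oxidative phosphorylation (−0.0010, 0.701) were not called. Germline and cancer-testis genes, which G9a represses in other cells, had 2 of 6 measured members higher (median −0.34, mean −0.048, 0.701). Clustered protocadherins had a median of −0.10, while the test pointed up (0.701), and with the filter at 1 CPM their median was 0.20 and the list was called (0.00515). Imprinted genes had a median of −0.0077 and a mean of 0.00073, and the test pointed down (0.522). Immune cell markers and endothelial markers had 3 measured members each, too few for the test. Their medians were 0.038 and 0.58 in shG9a_1, and −0.091 and 0.14 in shG9a_4.

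Hairpin shG9a_4 was compared with shSCR as a second sequence against the same mRNA, with the smaller change of EHMT2. The genes that rose were PRDX3 (log2 fold change 0.70, SE 0.09, adjusted p = 0.0478 in edgeR), RAB21 (0.68, SE 0.08, 0.0415), TRIM37 (0.67, SE 0.07, 0.0337), ANO6 (0.53, SE 0.07, 0.0415) and CCDC25 (0.51, SE 0.07, 0.0452). PRDX3 was at 337 ± 39.6 CPM in shG9a_4 and RAB21 at 127.7 ± 12.7 CPM (SD, n = 3 each). These 5 genes were all the calls among 18435. Unadjusted p-values under 0.05 were found for 438 genes, or 903 with the block, where chance gives 922. The fit without the block counts the pairing by number as spread, so 922 is no exact mark for it. The groups did not overlap for 1185 genes (6.43%, where chance gives 10%). Without any 1 of 8 libraries the count was 0, with adjusted p-values of the 5 genes of 0.0779 to 0.448, and without shG9a_4 replicate 3 it was 7. The count was also 0 with only the 2 groups compared, and 1 (TRIM37) with unstranded counts. DESeq2 called 22 genes, the likelihood ratio test 17, no filter 49 and voom 5.

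With the block, 14 genes passed in shG9a_4 (13 higher, 1 lower), the 5 above among them. HOXA5, a homeobox factor, was at 12.8 ± 2.71 CPM in shSCR and 22.2 ± 6.18 CPM in shG9a_4, with a log2 fold change of 0.79 (adjusted p = 1.00 in edgeR, or 0.00974 with the block, in a range over settings of 1.02e-06 to 1). CYLD, a deubiquitinase that restrains NF-kB, had one of 0.61 (0.270, or 0.00974, in a range of 7.88e-08 to 1), and RHEB, the GTPase that activates mTORC1, one of 0.49 (0.104, or 0.0101, in a range of 3.67e-05 to 0.673). KRT14 was at 0.70 (1.00, or 0.0148, in a range of 3.87e-09 to 1). PTGS2, the single gene lower, was at −0.89 (1.00, or 0.0224, in a range of 2.99e-11 to 1). The blocked count was 1 without shSCR replicate 1, 1 without shSCR replicate 2, 7 without shSCR replicate 3, 26 without shG9a_1 replicate 2 and 1 without shG9a_4 replicate 1.

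Among the lists, 14 of 28 were called in shG9a_4 by camera, 8 higher and 6 lower, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05. The count of lists was 7 without shSCR replicate 1, 8 without shG9a_4 replicate 2 and 9 without shG9a_4 replicate 3. Basal and myoepithelial genes rose as a set (20 higher, 5 lower, median 0.21, adjusted p = 9.49e-07), at adjusted p = 0.682 with an estimated correlation. COL17A1 was at 0.44 (SE 0.13), the desmosomal cadherin DSC3 at 0.26 (SE 0.10) and the integrin chain ITGA6 at 0.30 (SE 0.13). DNA replication and G1/S genes fell as a set (3 higher, 43 lower, median −0.067, adjusted p = 5.16e-05), at adjusted p = 0.682 with an estimated correlation. PCNA, the sliding clamp of DNA replication, went against its list at 0.22 (SE 0.07). These calls held without each library in turn. Replication-dependent histone genes fell as a set (1 higher, 27 lower, median −0.12, adjusted p = 1.73e-06), at adjusted p = 0.682 with an estimated correlation, and without shG9a_4 replicate 2 the median turned to 0.025 (0.905, in a range over settings of 5.80e-09 to 0.905). MYC-activated genes fell as a set (7 higher, 49 lower, median −0.048, adjusted p = 0.000423), at adjusted p = 0.682 with an estimated correlation, and the call was lost without shG9a_4 replicate 2 (0.0503) or replicate 3 (0.111), in a range of 3.17e-07 to 0.111. CCND2, a cyclin of that list, was at 0.41 (SE 0.11). Ribosome biogenesis genes fell as a set (4 higher, 37 lower, median −0.046, adjusted p = 0.000749), at adjusted p = 0.682 with an estimated correlation, and were not called without shG9a_4 replicate 3 (0.423, in a range of 5.13e-06 to 0.423). NOP16, a nucleolar protein, was at −0.14 (SE 0.06). Cytosolic ribosomal proteins fell as a set (8 higher, 39 lower, median −0.046, adjusted p = 0.00298), at adjusted p = 0.682 with an estimated correlation. Their call was lost without shSCR replicate 1 (0.0912), shSCR replicate 2 (0.107), shG9a_4 replicate 2 (0.0503) or shG9a_4 replicate 3 (0.568), in a range of 2.67e-06 to 0.568.

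MYC-repressed genes rose as a set in shG9a_4 (31 higher, 13 lower, median 0.053, adjusted p = 0.0300 in camera), at adjusted p = 0.682 with an estimated correlation. That call was lost without shSCR replicate 1 (0.302), and without shG9a_4 replicate 2 the median was −0.0058 (0.752, in a range over settings of 0.00321 to 0.752). Interferon-stimulated genes rose as a set (40 higher, 10 lower, median 0.082, adjusted p = 0.000391), at adjusted p = 0.682 with an estimated correlation, and were not called without shG9a_4 replicate 2 (0.309, in a range of 1.23e-05 to 0.309). PSMB8, IFI27 and IFI44 were at 0.18 (SE 0.07), 0.72 (SE 0.29) and 0.28. The p53 targets rose as a set (24 higher, 6 lower, median 0.062, adjusted p = 0.0133), at adjusted p = 0.682 with an estimated correlation. FAS, a death receptor, was at 0.23 (SE 0.08), and the call was lost without shSCR replicate 1 (0.207), shSCR replicate 3 (0.105) or shG9a_4 replicate 1 (0.798), in a range of 0.000173 to 0.798. Serine and one-carbon synthesis genes fell as a set (2 higher, 12 lower, median −0.092, adjusted p = 0.0300), at adjusted p = 0.682 with an estimated correlation, and the call was lost without shSCR replicate 1 (0.893), shG9a_4 replicate 2 (0.175) or shG9a_4 replicate 3 (0.111), in a range of 0.00212 to 0.893.

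Cholesterol biosynthesis genes rose as a set in shG9a_4 (20 higher, 4 lower, median 0.093, adjusted p = 0.00159 in camera), at adjusted p = 0.705 with an estimated correlation. STARD4, a sterol carrier, was at 0.29 (SE 0.09) and MSMO1, a sterol oxidase, at 0.32 (SE 0.13). That call was lost without shSCR replicate 2 (0.496), and without shG9a_4 replicate 3 the median was −0.031 (0.969, in a range over settings of 6.29e-07 to 0.969). The unfolded protein response rose as a set (17 higher, 4 lower, median 0.045, adjusted p = 0.0334), at adjusted p = 0.682 with an estimated correlation. It was not called without shSCR replicate 1 (0.181), shSCR replicate 3 (0.234) or shG9a_4 replicate 2 (0.752), with no filter (0.0524) or with unstranded counts (0.0772), in a range of 0.00315 to 0.752. Epithelial junction and luminal genes rose as a set (20 higher, 8 lower, median 0.083, adjusted p = 0.0346), at adjusted p = 0.752 with an estimated correlation. Without shSCR replicate 2 or shG9a_4 replicate 3 the epithelial median turned to −0.025 (0.970) or −0.074 (0.583), and the call was also lost without shSCR replicate 1 (0.383), with no filter (0.0879) and with unstranded counts (0.0605), in a range of 3.16e-07 to 0.970. Mitochondrially encoded genes rose as a set (13 higher, 0 lower, median 0.17, adjusted p = 0.0257), at adjusted p = 0.752 with an estimated correlation, MT-ND1 among them at 0.22 (SE 0.19). The share of reads on these genes was 0.887% in shG9a_4 replicate 3, the highest of the 9 libraries, and 0.537% in the lowest. Without that replicate the median was −0.14 and the list was called lower (0.00315), and without shSCR replicate 1 (0.136) or replicate 2 (0.645) it was not called, in a range of 1.65e-08 to 0.645.

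The other lists did not pass in shG9a_4, and single libraries moved many of them past the threshold in camera. Inflammatory and NF-kB targets (19 higher, 15 lower, median 0.018, adjusted p = 0.670) were called higher without shSCR replicate 2 (median 0.27, 6.53e-07) or shG9a_4 replicate 3 (0.19, 0.00315), and lower without shG9a_4 replicate 2 (−0.14, 0.0166). Mesenchymal and matrix genes (18 and 18, −0.00088, 0.898) were called higher without shSCR replicate 2 (0.083, 0.00212). The H3K9 methylation machinery (−0.032, 0.0678) was called lower with the block (0.0362, or adjusted p = 0.515 with an estimated correlation), upper-quartile scaling (0.0428), the filter at 1 CPM (0.0223) or unstranded counts (0.0456), and without shSCR replicate 2 (0.0326), shSCR replicate 3 (0.0226) or shG9a_4 replicate 1 (0.0418). Fibroblast markers (0.15, 0.119) were called higher with the block (0.0187, or adjusted p = 0.374 with an estimated correlation) and without shSCR replicate 2 (0.00212), shG9a_1 replicate 1 (0.0499) or shG9a_4 replicate 1 (0.00822), and epidermal differentiation genes (0.064, 0.148) with the block (0.0309, or adjusted p = 0.374 with an estimated correlation) and without shSCR replicate 2 (0.00803). ATF4 and amino acid response genes (−0.021, 0.199) were called without shSCR replicate 2 (0.00720) or shG9a_4 replicate 1 (0.0330), and fatty acid synthesis (0.040, 0.157) without shSCR replicate 3 (0.0131) or shG9a_4 replicate 1 (0.0330). Hypoxia and glycolysis genes (−0.027, 0.525) were called without shSCR replicate 3 (0.000677), and oxidative phosphorylation (−0.013, 0.175) without shG9a_4 replicate 1 (0.00822).

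Imprinted genes (median 0.078, adjusted p = 0.878 in camera) and autophagy and lysosome genes (0.0070, 0.670) were not called in shG9a_4 under any setting tried. G2/M and mitosis genes had 32 members higher and 16 lower (median 0.028, 0.157), with NUF2, a kinetochore protein, at 0.26 (SE 0.06), and were called without shG9a_4 replicate 1 (0.0364). Germline genes had a median of 0.031 and a mean of −0.020 and the test pointed down (0.811), and clustered protocadherins had a median of −0.014 while the test pointed up (0.878), with a call at a filter of 1 CPM (median 0.059, 0.000386). Of 818 list members, 0 passed over all genes in edgeR and 0 when adjusted over the list alone, 25 had an unadjusted p under 0.05, and DESeq2, voom and the likelihood ratio test called 0 each. With the block, KRT14 rose and PTGS2 fell over all genes, and 17 members passed when adjusted over the list alone (14 higher, 3 lower), with 9 basal, 3 MYC-repressed and 2 cholesterol genes higher.

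**Figure D2:**
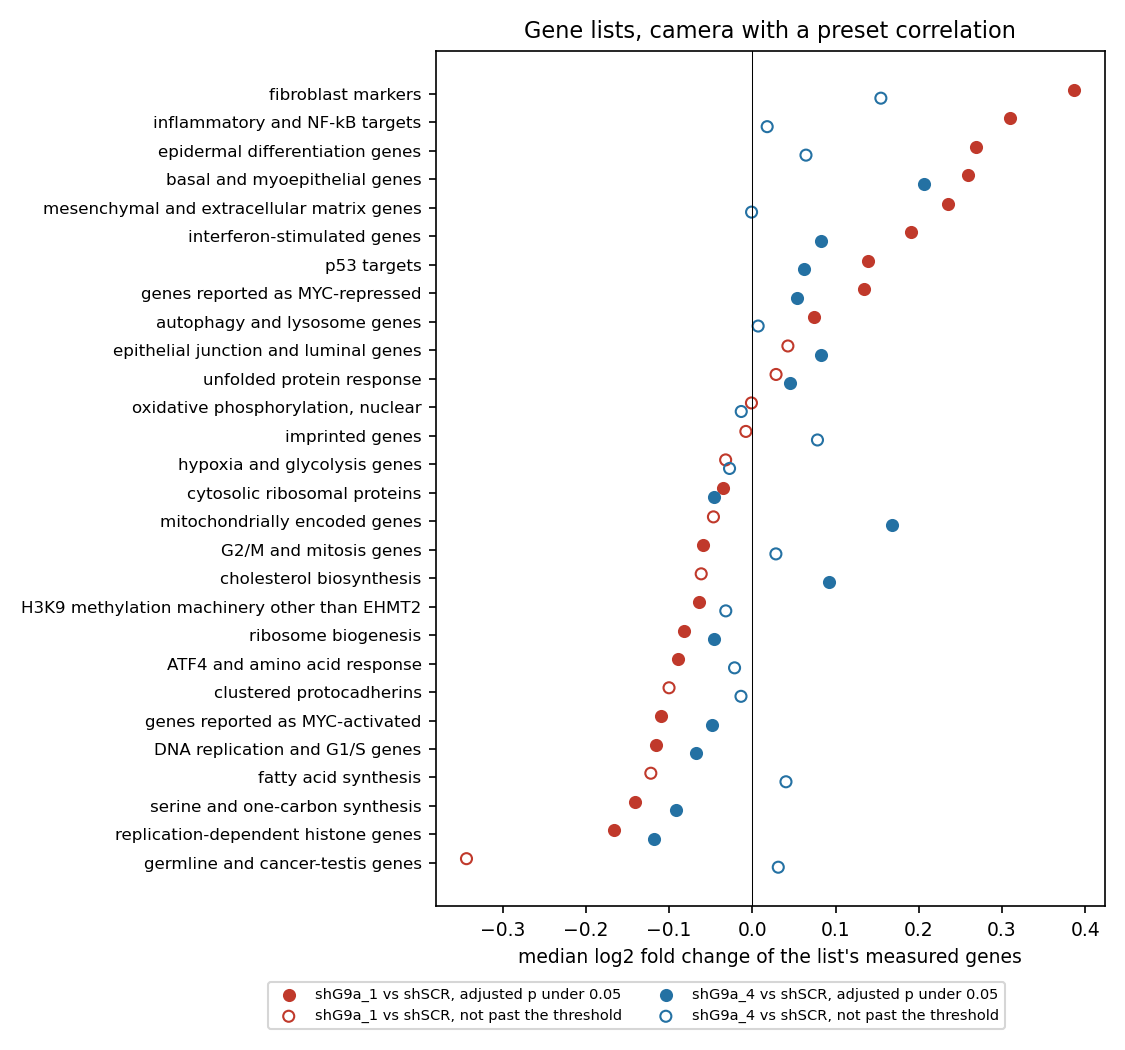
Median log2 fold change against shSCR of the measured members of each of the 28 tested lists, red for shG9a_1 and blue for shG9a_4, with filled points where the camera test at the preset correlation gave an adjusted p under 0.05. Filled points number 18 in shG9a_1 and 14 in shG9a_4, and 0 in each with an estimated correlation.

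The hairpins were also compared for what they shared. PRDX3, RAB21, TRIM37, ANO6 and CCDC25 rose in both, and each lay higher in all 6 knockdown libraries than in all 3 shSCR libraries. No gene fell in both in the main fit, while EHMT2 did with DESeq2. With the block, 13 genes passed in both (12 higher, 1 lower), among them RHEB, CYLD, PIK3CA, KRT14, HOXA5 and, lower, PTGS2. Independent sets of calls would share 0.00163 genes, or 0.0839 higher and 0.00130 lower with the block, which leaves out the shared controls. Unchanged groups simulated against the same controls, fitted without the block, shared 0 in 20 data sets. The simulation drew each gene on its own and left out the pairing by replicate number, so neither value bounds what chance gives. Regroupings of the real libraries, without the block, shared up to 16 genes. The log2 fold changes of both hairpins correlated at 0.488 across genes, which are not independent replicates, against 0.482 to 0.507 in the simulations, and 67.7% of genes had the same sign, against a simulated mean of 66.6%. The covariance was 0.0311, below the 0.0334 to 0.0361 of the simulations. The 3 control libraries could not be divided into groups of more than 1, so part of the overlap of calls may come from the shared controls. The shared count of 5 was 0 without any 1 of 8 libraries and 6 without shG9a_4 replicate 3, and 0 with only the 2 groups compared. The blocked count of 13 was 1 without shSCR replicate 1, shSCR replicate 2 or shG9a_4 replicate 1, 4 without shSCR replicate 3, 21 without shG9a_1 replicate 2 and 3 without shG9a_1 replicate 3.

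**Figure D3:**
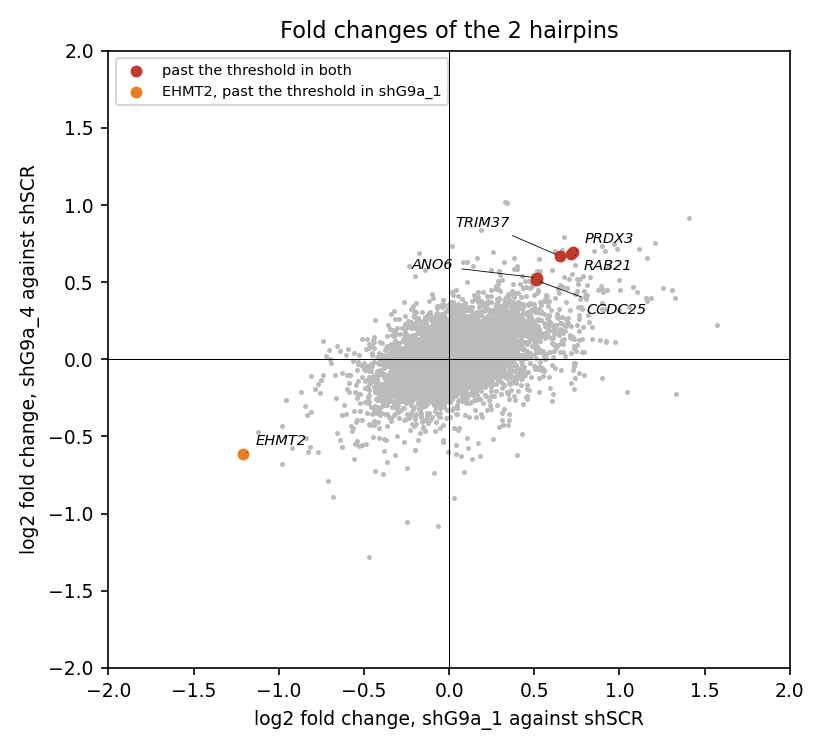
Log2 fold change of each gene of at least 1 CPM in shG9a_1 (x axis) and in shG9a_4 (y axis), each against shSCR, with red for the genes past the threshold in both and orange for EHMT2, which passed it in shG9a_1. The 5 red genes lie at 0.51 to 0.72 on both axes, and EHMT2 at −1.21 and −0.61.

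A direct comparison of shG9a_4 with shG9a_1 asked where the hairpins differed. EHMT2 was higher in shG9a_4 by a log2 difference of 0.60 (SE 0.11), with no overlap of the libraries, and missed the threshold in edgeR (adjusted p = 1.00, and 4.01e-05 to 1 over settings). Of 18435 genes, 0 passed in edgeR and 754 had an unadjusted p under 0.05, while DESeq2 called 6, the likelihood ratio test 5, voom 0 and no filter 106. The groups did not overlap for 1691 genes (9.17%, where chance gives 10%). With the block the count was also 0 in edgeR, with 1619 genes at an unadjusted p under 0.05 and 95 called by DESeq2. Leaving out shSCR replicates 1, 2 and 3 gave blocked counts of 7, 8 and 1, and leaving out shG9a_1 replicate 2 gave 17.

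Camera called 16 of 28 lists between the hairpins, 9 higher and 7 lower in shG9a_4, and 0 with an estimated correlation. Mesenchymal and extracellular matrix genes were lower in shG9a_4 (4 members higher, 32 lower, median −0.27, adjusted p = 2.64e-07), G2/M and mitosis genes higher (43 and 5, 0.091, 5.70e-06) and autophagy and lysosome genes lower (7 and 28, −0.058, 0.00267). Their values were adjusted p = 0.683, 0.683 and 0.202 with an estimated correlation, and these calls held without each library in turn. Inflammatory and NF-kB targets were lower (3 and 31, −0.23, 1.31e-05) and cholesterol biosynthesis genes higher (23 and 1, 0.15, 3.30e-05), at adjusted p = 0.683 each with an estimated correlation. Interferon-stimulated genes (−0.10, 0.00181), MYC-repressed genes (−0.079, 0.0112), p53 targets (−0.061, 0.0103) and epidermal differentiation genes (−0.14, 0.0388) were lower. MYC-activated genes (0.054, 0.00282), fatty acid synthesis (0.13, 0.0188), serine and one-carbon synthesis (0.085, 0.0197), ATF4 and amino acid response (0.062, 0.0142), G1/S genes (0.047, 0.0114), histone genes (0.066, 0.0161) and mitochondrially encoded genes (0.18, 0.0188) were higher. Each of these 11 lists was at adjusted p = 0.683 with an estimated correlation, except the histone genes at 0.787. Of 818 list members, 0 passed in edgeR over all genes or when adjusted over the list alone, 31 had an unadjusted p under 0.05, and DESeq2, voom and the likelihood ratio test called 0 each. With the block, 0 passed over all genes and 48 when adjusted over the list alone (14 higher, 34 lower), with 16 mesenchymal, 7 NF-kB and 5 MYC-repressed genes lower and 5 cholesterol and 4 epithelial genes higher.

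Single libraries carried many of these differences between the hairpins. Without shG9a_1 replicate 2 camera called 6 lists, and the lists lost were MYC-repressed (adjusted p = 0.0709), MYC-activated (0.249), interferon (0.0709), NF-kB (median −0.081, 0.119), fatty acid synthesis (0.286), serine (0.111), ATF4 (0.178), p53 (0.0605), G1/S (0.897), epidermal (0.458) and mitochondrially encoded genes (0.0709). Without shG9a_4 replicate 3 it called 8, and those lost were MYC-repressed (0.182), interferon (0.200), NF-kB (median −0.075, 0.182), cholesterol (0.275), fatty acid synthesis (0.353), serine (0.0652), p53 (0.467), histone (0.997) and epidermal genes (0.275). The mitochondrially encoded genes were then called lower in shG9a_4 (median −0.10, 0.0198). Without shG9a_4 replicate 1 it called 9, and those lost were MYC-repressed (0.243), MYC-activated (0.571), serine (0.204), ATF4 (0.317), G1/S (0.305), histone (0.722) and epidermal genes (0.258). Without shG9a_1 replicate 1 cholesterol (0.310), fatty acid synthesis (0.390), p53 (0.481), G1/S (0.0939), histone (median −0.046, 0.363) and epidermal genes (0.159) were lost, and without shG9a_1 replicate 3 mitochondrially encoded genes (0.0906). 

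Of the lists not called between the hairpins, camera called epithelial junction and luminal genes (median 0.084, adjusted p = 0.562) with the block (0.00728, or adjusted p = 0.446 with an estimated correlation) and without shG9a_1 replicate 3 (0.00935) or shG9a_4 replicate 2 (0.0394). Fibroblast markers (−0.17, 0.305) were called with the block (0.0152, or adjusted p = 0.296 with an estimated correlation) and without shG9a_4 replicate 2 (0.0248). Ribosome biogenesis genes (0.032, 0.0864) were called with the filter at 1 CPM (0.0475) and without shG9a_1 replicate 1 (0.00422) or shG9a_4 replicate 3 (0.00390), and hypoxia and glycolysis genes (0.047, 0.571) without shG9a_1 replicate 2 (0.04999). The H3K9 machinery (0.044, 0.562), basal genes (−0.056, 0.761), protocadherins (−0.034, 0.829), imprinted genes (0.025, 0.428) and oxidative phosphorylation (−0.021, 0.562) were called in no setting tried. The unfolded protein response (−0.0028, 0.706), germline genes (−0.0076, 0.853) and ribosomal proteins (0.0045, 0.850) had a test that pointed opposite to the median, and germline genes were called higher with unstranded counts (0.0435).

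The authors' deposited tables of each hairpin against shSCR hold 11015 entries each, of which 267 for shG9a_1 and 270 for shG9a_4 carry no value. No entry with a value was found in them under the symbol EHMT2. In the authors' deposited table for shG9a_1, 322 genes had a posterior probability of different expression of at least 0.95 (124 higher, 198 lower), and in the authors' deposited table for shG9a_4 66 did (44 higher, 22 lower). PRDX3, RAB21, TRIM37, ANO6, CCDC25 and RHEB had a probability of 1 in both of the authors' deposited tables. In the authors' deposited tables MEST had 1 for shG9a_1 and 0.383 for shG9a_4, and TP53I3 0.996 and 0.000548. In the authors' deposited tables the unsmoothed folds of PRDX3 came to log2 values of 0.71 and 0.69, and those of TRIM37 to 0.64 and 0.67. Of the genes at 0.95 or more in the authors' deposited tables that could be matched, 6 of 311 for shG9a_1 and 5 of 62 for shG9a_4 were called here by edgeR, and 32 and 7 with the block. Across 9040 and 9039 matched genes, which are not independent replicates, the log2 folds of the authors' deposited tables and those computed here had the same sign for 94.7 and 95.1%, with Pearson correlations of 0.920 and 0.921.

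Shares of read pairs outside genes did not separate the groups. Pairs with no feature made up 13.5 ± 0.446% in shSCR, 13.0 ± 0.614% in shG9a_1 and 13.8 ± 1.63% in shG9a_4, and unmapped pairs 3.50 ± 0.739, 3.15 ± 0.465 and 3.38 ± 0.822% (SD, n = 3 each). For these and the ambiguous and multimapped shares, exact two-sided permutation tests of each hairpin against shSCR gave p-values of 0.4 to 1.0, where 0.1 is the smallest that 3 against 3 allows, and 1 after adjustment over the 8 tests.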

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

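The tests of other splits of the libraries, and those that take 1 library of each replicate number, were chosen only after the results were seen, while the tests of the inflammatory and matrix genes over all choices of 3 libraries were written before.

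A difference between the hairpins, by the camera test of shG9a_4 against shG9a_1, singled out 16 gene lists. Median log2 differences were −0.27 for mesenchymal and extracellular matrix genes, −0.23 for inflammatory and NF-kB targets, −0.14 for epidermal differentiation genes, −0.10 for interferon-stimulated genes, −0.079 for MYC-repressed genes, −0.061 for p53 targets and −0.058 for autophagy and lysosome genes. They were 0.18 for mitochondrially encoded genes, 0.15 for cholesterol biosynthesis, 0.13 for fatty acid synthesis, 0.091 for G2/M and mitosis genes, 0.085 for serine and one-carbon synthesis, 0.066 for histone genes, 0.062 for the ATF4 and amino acid response, 0.054 for MYC-activated genes and 0.047 for DNA replication and G1/S genes. With an estimated correlation camera called 0 lists, 1 at an unadjusted p under 0.05. The calls of mesenchymal, G2/M and autophagy genes held without each of the 9 libraries in turn, and the report names the libraries without which the others were lost.

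Inflammatory and NF-kB targets were higher in shG9a_1 than in the other libraries, and a candidate explanation is variation between single libraries. Their scores in replicates 1, 2 and 3 were −0.20, 0.37 and −0.45 in shSCR, 0.28, 0.43 and −0.23 in shG9a_1, and −0.097, 0.41 and −0.51 in shG9a_4, so that shG9a_1 was highest within each number. Of the 84 choices of 3 libraries a share of 0.393 gave a difference as large as the real one of 0.241 (highest other 0.607), but these choices mix in the variation between the numbers, and of the 27 that take 1 library of each number the share was 0.0370 (highest other 0.228). Variation between libraries cannot be told apart from an effect of shG9a_1: the list was picked for its result, 7 of the 84 pairs of a list and a group reached that share (6 of them among the 28 lists in shG9a_1, which goes against such variation but rests on the same libraries each time), and with the block the list passed at the preset correlation (1.86e-12) and not at an estimated one (0.0874). An effect of shG9a_1 that has nothing to do with EHMT2 was not tested apart from it.

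Mesenchymal and extracellular matrix genes were also higher in shG9a_1 than in the other libraries, and fibroblast markers with them, by medians of 0.39 (0.0234, or 9.24e-05 with the block) in shG9a_1 and 0.15 in shG9a_4, and of −0.17 (0.305, or 0.0152 with the block) between the hairpins, calls lost with an estimated correlation (adjusted p = 0.324, and 0.0971 and 0.296 with the block). The scores of the matrix genes were −0.27, 0.18 and −0.12 in shSCR, −0.025, 0.25 and 0.22 in shG9a_1, and −0.19, 0.099 and −0.14 in shG9a_4, with shG9a_1 again highest within each number. The share of choices as large as the real difference of 0.227 was 0.119 of all 84 (highest other 0.330) and 0.0370 of the 27 with 1 library of each number (highest other 0.190). Variation between libraries cannot be told apart from an effect of shG9a_1 here either, for the same reasons, with blocked values of 1.06e-11 at the preset and 0.0874 at an estimated correlation. Whether such an effect comes from the loss of EHMT2 was not tested, and other cells among the cultures stay open.

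The counts of changed genes were set against other splits of the same libraries. For shG9a_1, 1 of the 10 splits gave as many genes as the real 7 (highest other 0) and 1 of 10 as many lists as the real 18 (highest other 17). For shG9a_4, 1 of 10 gave as many genes as the real 5 (highest other 0) and 4 of 10 as many lists as the real 14 (highest other 17). Between the hairpins each of the 10 splits gave 0 genes by edgeR, as the real split did (highest other 0; 754 at an unadjusted p under 0.05, and 6 by DESeq2), and 1 of 10 gave as many lists as the real 16 (highest other 15). With the block, among the 4 splits that part all 3 numbered pairs, 1 gave as many genes as the real 143 in shG9a_1 (highest other 0), 1 as many as the real 14 in shG9a_4 (highest other 0) and all 4 as many as the real 0 between the hairpins (highest other 0). For lists, the other splits that part all 3 pairs gave 17, 9 and 9 in shG9a_1, 5, 4 and 11 in shG9a_4 and 7, 2 and 4 between the hairpins, and the 3 others in shG9a_4 with as many as the real split (17, 16 and 16) part 1 pair each and so put libraries of the same number together. These splits are too few for a share under 0.05.

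For the genes shared by both hairpins, 6 of 100 drawn regroupings of the 9 libraries, the real one included, gave 5 or more, with 16 as the highest other, so chance is not excluded for that count. Of the 5 others, 3 took as controls the libraries of a single replicate number (16 and 13 genes with replicate 2, 10 with replicate 1), which points to a structure of the samples by that number, and the other two kept the shSCR libraries as controls. With the replicate block, 1 of 100 regroupings that part the numbers in the same way, the real one, gave as many as the real 13. That share lies under 0.05, but the highest others, 12 and 10, came from regroupings that kept the shSCR libraries as controls and mixed the hairpins. The count therefore sets the shSCR libraries apart from the rest, and does not tell genes shared by both hairpins from an effect of the shared controls.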

How the results depend on the processing

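A newer deviance in edgeR and all settings within the blocked fit other than the block itself were chosen only after the data were seen.

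The report gives the calls that the replicate block changed among the genes it names and the lists, and the block changed no other call of these. The log2 fold changes of named genes, 98 results with 1953 values under the alternatives, kept their direction and side of the threshold in 1756, were weaker in 88, stronger in 99 and reversed in 10. For the medians of lists, 84 results with 1508 values, these counts were 1209, 174, 43 and 82. RLE scaling, the filter at 1 CPM in 3 libraries, voom and the newer deviance gave 7, 9, 7 and 7 genes in shG9a_1 and 5 each in shG9a_4 and in both. Depth was 53065611 reads in genes or more per library. The squared differences between replicates were 25.2 to 78.9 times those of counting error, a mean over genes with at least 20 reads in which genes of many reads weigh most. For such genes the spread between cultures exceeded counting error, while for genes of few reads the mean does not tell the one from the other. The median SE was 0.154 over the genes tested. Genes under the filter are limited by depth and got no test outside the setting without it.

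Without the filter on low counts 288 genes passed in shG9a_1, 49 in shG9a_4, 106 between the hairpins and 29 in both. Of these, 287, 49 and 106 lay inside the filtered set, and the estimate of prior degrees of freedom became unbounded, from a median of 4.83, so nearly all of the change came with the estimate of the spread and not from added genes. The counts were 79, 22, 6 and 18 with DESeq2 and 42, 17, 5 and 14 with the likelihood ratio test, whose models take no account of the uncertainty of the spread as the quasi-likelihood test does. Unstranded counts gave 1 in shG9a_4 and 1 in both, where the cause was not tested. With only the 2 groups compared these counts were 0 and 0, with 347 genes at an unadjusted p under 0.05 in shG9a_4, and fewer libraries then estimated the spread. The replicate block gave 143, 14 and, in both, 13. Among lists, fry gave 1, 0 and 0 (6, 0 and 1 at an unadjusted p under 0.05), where the cause was not tested. An estimated correlation gave 0, 0 and 0 (4, 0 and 1), also for autophagy genes, whose estimate in shG9a_1 was −0.0123, under the preset value. A lower correlation alone would not lose their call, and that setting also rests on the 6 residual degrees of freedom of the fit. How far each of these moved the other lists was not tested. Within the blocked fit DESeq2 gave 440, 46, 95 and 35 genes, and upper-quartile scaling 70 in shG9a_1, where the cause was not tested.

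Without single libraries the camera test of a list turned in direction in 73 cases, 4 of them past the threshold: NF-kB targets in shG9a_4 without shG9a_4 replicate 2 (median −0.14, adjusted p = 0.0166), mesenchymal genes in shG9a_4 without shSCR replicate 2 (0.083, 0.00212) and, without shG9a_4 replicate 3, mitochondrially encoded genes in shG9a_4 (−0.14, 0.00315) and between the hairpins (−0.10, 0.0198). Under the other settings, with all 9 libraries or only the groups compared, it turned in 9 cases, with a lowest adjusted p of 0.692, and the cause was not tested. The median itself changed sign in 3 of them. Without the filter the median was 0.020 for mesenchymal genes and −0.030 for protocadherins in shG9a_4 and −0.037 for germline genes between the hairpins. With unstranded counts it was −0.0050 for germline genes in shG9a_4 and 0.027 for protocadherins between the hairpins. With only the groups compared it was −0.12 and −0.020 for protocadherins in shG9a_1 and shG9a_4, and with the replicate block −0.34 and 0.013 for germline genes in shG9a_1 and shG9a_4.

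Leaving out each library in turn gave 0 to 10 genes in shG9a_1, 0 to 7 in shG9a_4 and 0 to 6 in both. The counts were 8, 7 and 6 without shG9a_4 replicate 3, 10 in shG9a_1 without shG9a_4 replicate 2, and otherwise 0 or 1. Lists numbered 7 to 19 in shG9a_4 and 6 to 18 between the hairpins. With the block the counts were 4 to 549, 1 to 26, 0 to 17 between the hairpins and 1 to 21 in both. Log2 fold changes ran from −0.052 to 0.023 for EHMT1 and −0.099 to 0.040 for MYC in shG9a_1. In shG9a_4 they ran from −0.11 to 0.054 for EHMT1, −0.21 to 0.18 for WIZ, −0.16 to 0.11 for MYC and −0.082 to 0.44 for MT-ND1. Folds that kept their sign but moved by over 1.5 times ran in shG9a_1 from 0.033 to 0.25 for WIZ, −0.12 to −0.019 for ZNF644, 0.51 to 1.20 for KRT14, −1.07 to −0.25 for PTGS2, 0.16 to 0.48 for COL17A1, 0.19 to 0.45 for RELB, 0.28 to 0.57 for SAA1, −0.50 to −0.15 for PHGDH, −0.33 to −0.12 for PSAT1, −0.39 to −0.20 for ASNS, −0.33 to −0.16 for ATF4, −0.48 to −0.26 for H2BC14, 0.17 to 0.37 for CTSB, 0.80 to 1.60 for SPRR2A and 0.76 to 1.40 for PTHLH. Those in shG9a_4 ran from −0.35 to −0.17 for ZNF644, 0.43 to 1.04 for KRT14, −1.29 to −0.47 for PTGS2, 0.47 to 0.93 for IFI27, 0.17 to 0.42 for ITGA6 and 0.15 to 0.35 for DSC3.

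In the same way, medians in shG9a_1 ran from −0.082 to 0.0036 (hypoxia), −0.47 to −0.14 (germline), −0.014 to 0.016 (oxidative phosphorylation), −0.081 to 0.24 (epithelial), −0.22 to 0.060 (cholesterol), −0.24 to 0.028 (fatty acid), −0.27 to 0.10 (protocadherins) and −0.17 to 0.10 (mitochondrially encoded). In shG9a_4 they ran from −0.14 to 0.27 (NF-kB), −0.064 to 0.033 (ATF4), −0.075 to 0.031 (hypoxia), −0.20 to 0.26 (germline), 0.0012 to 0.032 (autophagy), −0.045 to 0.11 (fatty acid), −0.092 to 0.083 (mesenchymal), −0.034 to 0.082 (imprinted), −0.12 to 0.086 (protocadherins), −0.010 to 0.053 (G2/M), −0.20 to 0.025 (histones), −0.033 to 0.13 (epidermal), −0.031 to 0.20 (cholesterol), −0.074 to 0.32 (epithelial), −0.14 to 0.34 (mitochondrially encoded) and −0.044 to 0.0073 (oxidative phosphorylation).

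Between the hairpins they ran from −0.090 to 0.12 (protocadherins), −0.11 to 0.29 (germline), −0.046 to 0.20 (histones), −0.073 to 0.19 (epithelial), −0.024 to 0.039 (ribosomal proteins), −0.037 to 0.010 (oxidative phosphorylation), 0.0060 to 0.066 (ribosome biogenesis), −0.037 to 0.035 (unfolded protein response), −0.032 to 0.088 (hypoxia), −0.18 to 0.086 (basal), −0.36 to 0.074 (fibroblast), −0.030 to 0.045 (imprinted) and −0.10 to 0.32 (mitochondrially encoded). Differences in shares of read pairs, in percentage points, ran in shG9a_4 from −0.531 to 1.096 (no feature), −0.0396 to 0.0535 (ambiguous), −0.330 to 0.126 (multimapped) and −0.591 to 0.295 (unmapped), and in shG9a_1 from −0.0291 to 0.0175 (ambiguous) and −0.629 to 0.0658 (unmapped).

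Medians of called lists that a single library moved by over 1.5 times were, in shG9a_1, H3K9 −0.031, NF-kB 0.18, ATF4 −0.045, basal 0.14 without shSCR replicate 1. Without shSCR replicate 2: ribosome biogenesis −0.054, NF-kB 0.64, mesenchymal 0.41, basal 0.14, ribosomal proteins −0.0086. Without shSCR replicate 3: NF-kB 0.15, mesenchymal 0.15, ribosomal proteins −0.062, fibroblast 0.24. Without shG9a_1 replicate 1: MYC-repressed 0.21, G2/M −0.030, histones −0.062. Without shG9a_1 replicate 2: ribosome biogenesis −0.041, NF-kB 0.10, G2/M −0.028, mesenchymal 0.13, epidermal 0.15. Without shG9a_1 replicate 3: NF-kB 0.53, G2/M −0.12, histones −0.26, basal 0.12, ribosomal proteins −0.023. In shG9a_4 such medians were cholesterol 0.053, serine −0.016, p53 targets 0.035, epithelial 0.040 without shSCR replicate 1. Without shSCR replicate 2: MYC-repressed 0.11, cholesterol 0.011, unfolded protein response 0.078, epithelial −0.025, basal 0.11, mitochondrial 0.043. Without shSCR replicate 3: cholesterol 0.20, unfolded protein response 0.013, p53 targets 0.038, epithelial 0.32, mitochondrial 0.27, ribosomal proteins −0.079. Without shG9a_4 replicate 1: MYC-repressed 0.086, cholesterol 0.16, p53 targets 0.015, basal 0.13, mitochondrial 0.34, ribosomal proteins −0.071. Without shG9a_4 replicate 2: MYC-repressed −0.0058, interferon 0.029, unfolded protein response 0.015, histones 0.025, epithelial 0.22. Without shG9a_4 replicate 3: MYC-repressed 0.11, ribosome biogenesis −0.023, cholesterol −0.031, serine −0.060, unfolded protein response 0.083, p53 targets 0.13, histones −0.20, epithelial −0.074, basal 0.10, mitochondrial −0.14, ribosomal proteins −0.00047. Between the hairpins such medians were MYC-repressed −0.14, cholesterol 0.045, fatty acid 0.045, p53 targets −0.033, histones −0.046, epidermal −0.24 without shG9a_1 replicate 1. Without shG9a_1 replicate 2: MYC-activated 0.019, interferon −0.057, NF-kB −0.081, G1/S 0.013, G2/M 0.045, mesenchymal −0.12, autophagy −0.036. Without shG9a_1 replicate 3: NF-kB −0.43, cholesterol 0.30, fatty acid 0.26, p53 targets −0.13, G1/S 0.093, histones 0.14, epidermal −0.26. Without shG9a_4 replicate 1: MYC-repressed −0.023, MYC-activated 0.023, cholesterol 0.23, fatty acid 0.20, serine 0.045, ATF4 0.036, p53 targets −0.12, histones 0.015, mesenchymal −0.15, mitochondrial 0.32. Without shG9a_4 replicate 2: MYC-repressed −0.12, interferon −0.16, NF-kB −0.52, G2/M 0.038, histones 0.20, epidermal −0.32. Without shG9a_4 replicate 3: MYC-repressed −0.13, interferon −0.057, NF-kB −0.075, cholesterol 0.027, fatty acid 0.032, p53 targets −0.023, histones −0.031, autophagy −0.089, mitochondrial −0.10.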

Other observations

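Of the tests on 3' UTR words, the test of library-to-library variation was written before its result, and those of length and composition, of proportion to EHMT2 and of the control hairpin, with all other scan settings, were chosen only after the result was seen.

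The first principal component held 28.5% of the variance and set replicate 3 apart, at −27.6 in shSCR, −19.4 in shG9a_1 and −34.0 in shG9a_4. The next components held 17.2 and 12.7%.

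Genes whose 3' UTR carries the word CCTGAAA were higher in both knockdown groups than in shSCR, by 0.024 log2 for 2127 of 11394 genes searched, the highest z (7.57) of 15858 words, while among genes of at least 20 CPM another word, CCCTGAA, led (8.05). The mean deviation of these genes was −0.021, −0.0083 and −0.018 in the shSCR libraries, 0.011, 0.0096 and 0.0022 in shG9a_1, and 0.0062, 0.016 and 0.0022 in shG9a_4. The effect was 0.023 in shG9a_1 (z 5.53) and 0.024 in shG9a_4 (z 8.56). Found and tested on the same data, this is a hypothesis. In 28 of 50 random divisions of the genes the same word led in the discovery part. Over all 50, the word that led the discovery part, whichever it was, had a median z of 4.27 and a lowest of 0.497 in the test part. Both parts came from the same 9 libraries, so a difference between libraries would carry over from the discovery to the test part. Of the genes called in both hairpins 4 of 5 carry CCTGAAA, and 6 of 12 of those higher with the block, against 18.7% of all genes searched. These genes were part of the scan that picked the word, and the 18.7% is not matched for 3' UTR length or level. The shares are therefore no separate support.

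Against length or base composition as the whole cause, the highest z among the 414 other words of the same letters was 4.47. Against an effect in proportion to the loss of EHMT2 mRNA, the effect in shG9a_4 lay above that proportion (0.505, SE 0.0893) by 2.51 times its error between libraries, a thin margin over the t quantile of 2.45, and that error was widened after a value without it had been seen, while a saturating effect stays open. Variation between libraries and a sequence-directed effect of the control hairpin cannot be told apart from an effect of the knockdown. For the first, 1 of 84 choices of 3 libraries, and of the 27 with 1 library of each replicate number, reached the real z, which met the bound written beforehand, but the highest other was 7.39, and without length and GC terms, where other choices reach 33.5, the share as large was 0.798, so that bound was too loose to exclude it. For the second, the hairpins differed by 0.00063 log2 (z 0.183), as a cause in the shared controls would give, and the hairpin sequences are not given in the sources used here, so the word may or may not match them.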
